A study of Drosophila melanogaster with 2 samples.

How the data were processed

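Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos aged 0 to 4 hours that carried a transgene encoding CG4404 fused to enhanced green fluorescent protein, with an antibody against the fluorescent tag. Per the labels, chromatin was sheared by sonication to 200 to 800 bp, and there were 2 biological replicates of 1 group. No input or control library was analysed here, so enrichment rests on the peak calls of the authors.

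Per the file headers, the authors mapped to the dm6 assembly and deposited, for each replicate and for the replicates pooled, a ranked list of all candidate peaks and a thresholded list of the peaks that passed a test of irreproducible discovery rate (IDR), the expected share of peaks that do not recur between a pair of peak calls. The aligner, the peak caller and their versions are not given in the sources used here. The authors called peaks per replicate and on the pooled replicates; the pooled calls gave a conservative list, named so per the file headers, and a larger list, here called the optimal list. The deposited signal value of each peak is the peak caller's own, on a scale not given in the sources used here, and it was used only to describe, rank or filter peaks within one list. The deposited ranked lists also give the −log10 of the IDR, and every peak of the thresholded lists had an IDR of 0.01 or less, so 0.01 was taken as the threshold of the authors. Per the file headers, the thresholded lists were derived from the alignments and a further file of unstated kind. The pooled ranked list that compares the replicates holds a pair of signal values per peak, and these were treated as replicates without a number. The read depth of the libraries was not used here, and the number of peaks limits the precision.

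Coordinates are those of dm6, 1-based. Its sequence and the gene annotation (BDGP6, the same assembly) were taken from a reference copy, and 18277 annotated genes on the arms X, 2L, 2R, 3L, 3R, 4 and Y were used, 13968 of them protein-coding, with 23694 transcription start site (TSS) positions. Transposon records gave no TSS. Peaks off the 7 arms were left out of every comparison except the correlation of the replicates' signal values, which took in the whole conservative list, 54 of its peaks off the arms, and the whole ranked list. A summit was TSS-proximal when it lay within 500 bp of a TSS of any gene and distal otherwise, and a gene was bound when a summit lay within 500 bp of one of its TSSs. Each summit went into the first feature that applied among promoter, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic sequence.

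All tests were two-sided. Overlap of the replicates (at least 1 bp) was compared with 10000 random placements of the peaks of replicate 2 on the same arms. TSS proximity and features were compared with 10000 sets of random positions, as many per arm as there were summits, for which 0.0001 is the smallest p that permutation can give. Arms were compared by exact binomial tests, and gene lists, peaks of high and low signal, replicate-specific peaks and divergent genes by Fisher's exact test. Sequence was compared between a window of 100 bp either side of the summit and a window of equal width centred 500 bp away on the side of higher coordinates, by the exact McNemar test. Benjamini-Hochberg adjustment at 0.05 ran over the 7 features, the 7 arms, the 29 gene lists, the 24 motifs and the 32896 words of 8 bases. Between peaks of high and low signal it ran only over the 14 motifs that had passed at summits. Set against TSSs without a peak, motifs were counted at the 1489 summits within 500 bp of a protein-coding TSS and at 1 TSS of each protein-coding gene that was not bound, by Fisher's exact test. Shares carry 95% Wilson intervals, which cover counting error only, and peaks and neighbouring genes are not independent. P-values measure the spread over peaks, genes or positions, and none of them compares biological replicates. Of 403 list entries written as symbols or name patterns, 399 matched the annotation, of which SmG and nos matched another gene whose name differs only in case; the lists were kept so, and an alternative with such members put right was added after seeing the data. The lists, the motifs and the rule for named genes were fixed before the data were examined. The rule takes the 25 peaks of highest signal in the optimal list that overlap thresholded peaks of both replicates, each named by the nearest TSS and by protein-coding genes within 500 bp, CG4404 itself, up to 4 bound members with the highest signal of each list past the threshold and up to 2 of the other lists. Chemoreceptor and cuticle lists give counts only.

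The tests were also tried on simulated data. With 4000 simulated summits, a TSS-proximal share made to be 48.2% was recovered as 48.4%. The word CACTGAGA, planted in 461 windows, ranked number 1 among all words, and 0 words passed for random summits. The 1 enriched gene list, that of the ribosomal proteins, was found with 0 others. Both the word and the list also stand out in the real peaks, where the word lay in 182 windows. The simulation therefore tests only whether the code finds what was planted. Its random summits were not matched to the base composition of the peaks, so the 0 does not vouch for the words reported here. Alternatives covered the TSS window, peak list, background, overlap rule, motif window, flank, divergent distance and the list of each replicate alone. A stricter IDR of 0.01 had been planned, and because it is the threshold the authors used, an IDR of 0.001 was run in its place, chosen after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.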

Results

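The binding of CG4404, an uncharacterised Drosophila protein, was mapped by ChIP-seq of its GFP-tagged form in whole embryos aged 0 to 4 hours, in 2 biological replicates of a single group. The optimal pooled list held 3892 peaks and the conservative list 3741, and 3259 rows (87.1% of the conservative list) were identical in both. Replicate 1 alone gave 2982 peaks and replicate 2 gave 2539 (mean 2761 ± 313, SD, n = 2). On the arms, 3835 peaks of the optimal list covered 1299 kb, with a median width of 384 bp. Some of them overlap, and merged they made 3602 regions. Their signal, the peak caller's own value as the authors deposited it, ranged from 2.07 to 2755 over the list. In the whole list, 164 peaks had a signal under 20, while the median of all ranked peaks was 20.4. Peaks of such low signal were kept in the counts of peaks and bound genes.

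The tagged gene itself was examined first, because a transgene adds copies of it. CG4404 (FBgn0030432, X, 12903745 to 12906018, minus strand) had 2 peaks of the optimal list in or within 500 bp of the gene, the stronger at 12904295 to 12904678 with a signal of 56.2, rank 3597 among the 3835 peaks. The nearest summit of the optimal list lay 1324 bp from its TSS. The conservative list held 1 peak at the gene, the thresholded list of replicate 1 held 1, with a signal of 19.1, and that of replicate 2 held 0.

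The strongest peaks lay mostly at promoters. Of the 25 peaks of highest signal found in both replicates, 19 were promoter peaks and 18 had a protein-coding TSS within 500 bp. The highest signal, 2755, belonged to a peak 91 bp from the TSS of CG14100 (3L, 19590423 to 19590802, intergenic), with 1498 in the list of replicate 1 and 1267 in that of replicate 2. It was followed by a peak in an intron of Adf1, which encodes a sequence-specific transcription factor, at 2R, 6662842 to 6663259 (signal 2660), by one in an intron of the Polycomb gene ph-p at X, 2137162 to 2137549 (2530), 474 bp from its TSS, and by one upstream of the UDP-galactose transporter gene Ugalt at X, 2703698 to 2704088 (2294). A peak at 3L, 22878714 to 22879091 (1952) lay in the 5′ UTR of Chro, which encodes a chromodomain protein of polytene interbands, and also within 500 bp of the TFIIH subunit gene Ssl1. Of the 25 peaks, 9 lay within 500 bp of more than 1 protein-coding gene. These included the pairs Tcs5 and CHMP2B (signal 2156), Shc and Atat (1869), Art3 and mRpS10 (1832), CG7601 and CIA30 (1638), CG5611 and Mtl (1626), CenG1A and mRpS23 (1400), Pdrg1 and Pal1 (1306), and mRpL23 and CG9004 (1253). Single promoters in the set were those of px (2106), mRpL41 (1672), Sox14 (1553), CG1888 (1326), Fkbp14 (1195) and, beside asRNA:CR45928, the translation factor gene eIF6 (1196), and a peak of signal 1248 lay 492 bp from lncRNA:CR44619. Introns of CG32772 (1633), CG11050 (1629), HmgZ (1482) and Trl, the gene of the GAGA factor (1336), held 4 more. The remaining peak was intergenic, 3341 bp from the TSS of the cyclin gene CycB (1269).

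Both replicates gave largely overlapping peaks. Of the 2957 peaks of replicate 1 on the arms, 2063 (69.8%, 95% interval 68.1 to 71.4) overlapped a peak of replicate 2, and of the 2479 peaks of replicate 2, 2047 (82.6%, 81.0 to 84.0) overlapped one of replicate 1. Random placement gave a mean of 35.6 and at most 60 overlapped peaks of replicate 1 (permutation p = 0.0001). Peaks found by replicate 1 only had a median signal of 53.4 against 102 for its shared peaks. Across the 3741 peaks of the conservative list, the pair of signal values had a Spearman coefficient of 0.833 and a Pearson coefficient of 0.908 on the log2 scale. That list was selected for agreement between the same replicates, which in part fixes both coefficients, so they are no measure of reproducibility. These coefficients are across peaks, which are not independent replicates, and over all 131104 ranked peaks the Spearman coefficient was 0.296.

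**Figure D1:**
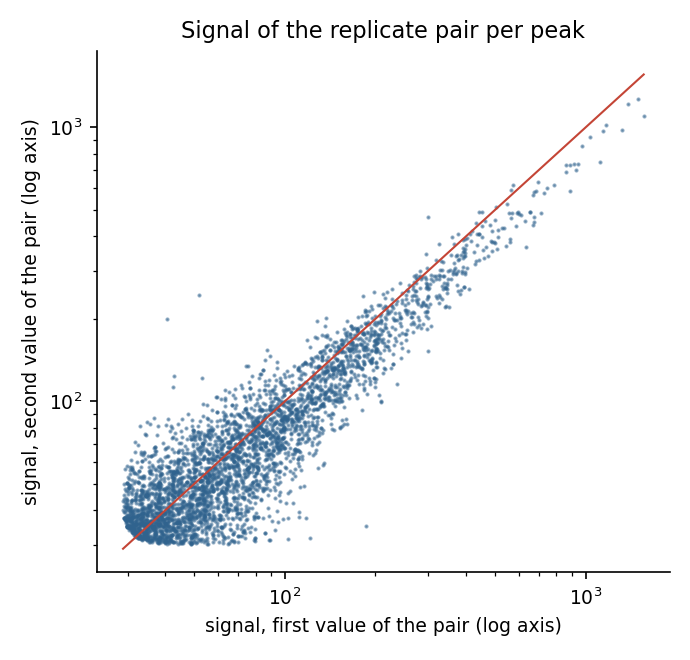
Signal of the replicate pair for each of the 3741 peaks of the conservative list, on log axes, with the line of equal values. The Spearman coefficient is 0.833 over these peaks, which were selected for agreement between the same replicates, and 0.296 over all 131104 ranked peaks.

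Binding was concentrated at promoters and scarce in coding sequence. Within 500 bp of a TSS lay 1592 of the 3835 summits (41.5%, 39.96 to 43.1), 3.06 times the 13.6% of random positions (permutation p = 0.0001). The lists of the replicates alone gave 48.0% and 44.3% (mean 46.1% ± 2.64, SD, n = 2). Coding exons held 129 summits (3.36%) against 13.7% of random positions, and 3′ UTRs held 26 (0.678%) against 4.43%. The coding exon share was lower still in replicate 1 alone (1.25%), in replicate 2 alone (0.968%) and at an IDR of 0.001 (0.216%). Introns, with 1287 summits (33.6%), and intergenic sequence, with 745 (19.4%), held less than the 39.5% and 27.3% of random positions. All 5 of these features passed (adjusted permutation p = 0.00014 each), whereas 5′ UTRs (19 summits, adjusted p = 0.063) and other exons (37 summits, adjusted p = 0.32) did not. In the lists of the replicates alone, 5′ UTRs did pass, with 0.237% of the summits of replicate 1 (adjusted permutation p = 0.001) and 0.323% of those of replicate 2 (adjusted permutation p = 0.014). They also passed, below random positions, with a promoter width of 250 bp (adjusted permutation p = 0.0082) or 1000 bp (0.0091), at an IDR of 0.001 (0.036) and with the left-out peaks put back (0.042). Against ranked peaks that did not pass they lay below as well (adjusted exact p = 0.0032), and with a promoter width of 250 bp other exons passed above random positions (adjusted permutation p = 0.0089). Each summit went into the first feature that applied, so the promoter excess leaves less for every other feature. The lower shares of introns, intergenic sequence and 5′ UTRs are therefore not read as avoidance of them.

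**Figure D2:**
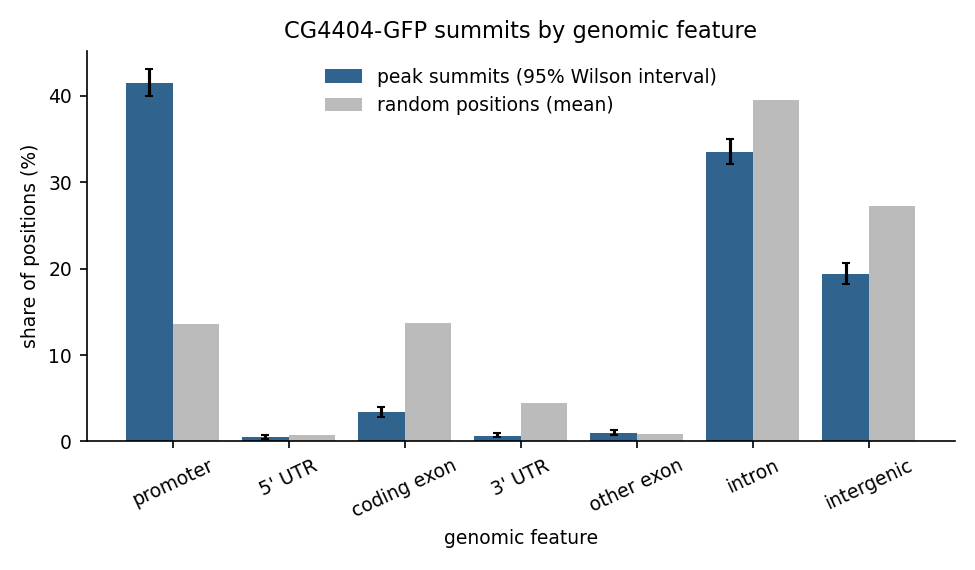
Share of the 3835 summits and of random positions in each genomic feature, in percent, with 95% Wilson intervals on the summits. Promoters hold 41.5% of the summits and 13.6% of random positions, and coding exons 3.36% and 13.7%.

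Genes for ribosomal proteins and for insulator and promoter proteins were bound more often than other genes. Among 13968 protein-coding genes, 1984 (14.2%) were bound. Of 93 ribosomal protein genes, 36 were bound (38.7%, 29.4 to 48.9, adjusted exact p = 3.2e-08), with the highest signals at RpL34b (517), RpL32 (413), RpS27 (341) and RpS20 (336). Of 29 genes for insulator and promoter proteins, 14 were bound (48.3%, 31.4 to 65.6, adjusted exact p = 3.6e-05), among them Chro (1952), the insulator cofactor gene Cp190 (620), pzg (509) and row (288). Fewer of them were bound in replicate 2 alone (8 of 29, 27.6%, adjusted exact p = 0.018) and at an IDR of 0.001 (9 of 29, 31.03%, adjusted p = 0.0059), and 13 in replicate 1 alone (44.8%). A peak can count in several lists. Named outside the rule, the peak of Nelf-E was also that of RpL14, and the peak of Dref that of RpL13. The proteasome gene Prosbeta2 likewise shared its peak with mRpL39 (187). Mitochondrial ribosomal protein genes were bound in 21 of 73 cases (28.8%, 19.7 to 40.01, adjusted exact p = 0.0029), with mRpS10 (1832), mRpL41 (1672), mRpS23 (1400) and mRpL23 (1253) the strongest. Splicing genes were bound in 11 of 35 cases (31.4%, adjusted exact p = 0.029), led by Sf3b6 (310), U2af50 (295), SF2 (228) and snRNP-U1-C (175). The entry SmG of that list had matched smg, a gene of a translational repressor, and with SNRPG in its place the count and the p were equal (11 of 35, adjusted exact p = 0.029). The splicing call did not hold in either replicate alone, where 14.3% (replicate 2, adjusted exact p = 0.64) and 25.7% (replicate 1, adjusted p = 0.092) were bound, nor in the conservative list (28.6%, adjusted p = 0.055) or at an IDR of 0.001 (17.1%, adjusted p = 0.46).

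None of the lists of embryonic patterning genes differed from other genes past the threshold. No gap gene (0 of 12, which allows a share of up to 25%, adjusted exact p = 0.56) and no pair-rule gene (0 of 9, up to 33.3%, adjusted p = 0.76) was bound. The early zygotic list had 2 of 32 bound, Sxl (159) and Ance (104) (adjusted exact p = 0.49), the segment polarity list 2 of 18, lin (105) and Wnt6 (65.3) (adjusted p = 1), and the Hox list 1 of 8, lab (114) (adjusted p = 1). Dorsoventral genes were bound in 4 of 33 cases, with tin (377) and htl (96.7) the strongest (adjusted exact p = 1), and maternal patterning and germ line genes in 6 of 36, with cact (235) and bcd (177) (adjusted p = 0.76). The entry nos of that list had matched Nos, the gene of nitric oxide synthase, and with nanos in its place 7 of 36 were bound (adjusted exact p = 0.47).

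Other lists of housekeeping and regulatory genes did not pass either. Polycomb and trithorax genes had 7 of 31 bound (22.6%, adjusted exact p = 0.35), yet ph-p (2530) and the chromatin remodeller gene brm (961) carried strong peaks. Cell cycle genes had 10 of 40 bound (25%, adjusted exact p = 0.15), including mei-41 (524) and Dp (403), proteasome genes 7 of 32, including Rpn5 (266) and Prosbeta2 (187) (adjusted p = 0.35), translation factor genes 11 of 52, including eIF6 (1196) and eIF3c (379) (adjusted p = 0.33), and DNA replication genes 7 of 36, including RnrS (420) and PolD2 (382) (adjusted p = 0.52). Oxidative phosphorylation genes had 13 of 84 bound, including ND-MWFE (477) and ND-ASHI (287) (adjusted exact p = 0.87), heat shock genes 5 of 26, including Hsp27 (858) and Hsc70-5 (216) (adjusted p = 0.56), and neuronal and muscle genes 3 of 27, including elav (848) and sls (189) (adjusted p = 1). The chorion and yolk list had 1 of 17 bound (adjusted exact p = 0.65), and that member was Cp190, an insulator gene that its name pattern took in. Without Cp190 and the centrosomal gene Cp110, 0 of 15 were bound (up to 20%, adjusted exact p = 0.31).

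Chemoreceptor, cuticle and histone genes and 5 of the 6 classes of RNA genes were bound less often than other genes. Chemoreceptor genes were bound in 0 of 164 cases, which allows a share of up to 1.83% (adjusted exact p = 2.6e-10), and cuticle protein genes in 1 of 122 (adjusted p = 1.2e-06). Among RNA genes, set against all other annotated genes, 5 of 290 tRNA genes (adjusted exact p = 1.6e-09), 7 of 269 snoRNA genes (adjusted p = 2.7e-07), 6 of 260 miRNA genes (adjusted p = 1.8e-07), 0 of 98 rRNA genes (up to 3.06%, adjusted p = 3.2e-05) and 114 of 1987 lncRNA genes (5.74%, adjusted p = 2.1e-20) were bound. The strongest were tRNA:Gln-TTG-2-1 (489), mir-9377 (287), snoRNA:Psi18S-920, whose peak (244) also lay at the TSS of RpL10Ab, and lncRNA:CR44463, whose peak (1672) was that of mRpL41. The strongest peak also lay within 500 bp of a protein-coding TSS for 3 of the 5 bound tRNA genes, 4 of the 7 snoRNA genes, 2 of the 6 miRNA genes and 28 of the 114 lncRNA genes. The annotated 5′ end of each gene was taken as its TSS, and some snoRNA and miRNA genes lie inside longer genes. Both snoRNA:Psi28S-2949 and snoRNA:Or-aca5 lie inside the lncRNA gene Uhg4, which has the same peak (164), and mir-275 lies inside lncRNA:CR43857. The low shares of snoRNA and miRNA genes are therefore not read as little binding at the promoters that transcribe them. The snRNA list had 1 of 32 bound, snRNA:7SKa (71.9, adjusted exact p = 0.33). Histone genes were bound in 2 of 115 cases (adjusted exact p = 3.2e-05), the variants His2Av (147) and His3.3B (105). In each replicate alone 3 tRNA genes and 0 cuticle genes were bound, in replicate 2 alone 2 miRNA genes, and in replicate 1 alone 1 histone gene. Of the 7 bound snoRNA genes, only snoRNA:Psi18S-920, snoRNA:Psi28S-2949 and snoRNA:Or-aca5 were also bound in replicate 2, and the last pair shared a peak. With a TSS window of 1000 bp the snoRNA call did not hold (10.8%, adjusted exact p = 0.18). Only 6 histone genes and 1 rRNA gene had any ranked peak at a TSS, both classes lie in near-identical copies, and against genes with a ranked peak neither call held (adjusted exact p = 0.58 and 1).

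**Figure D3:**
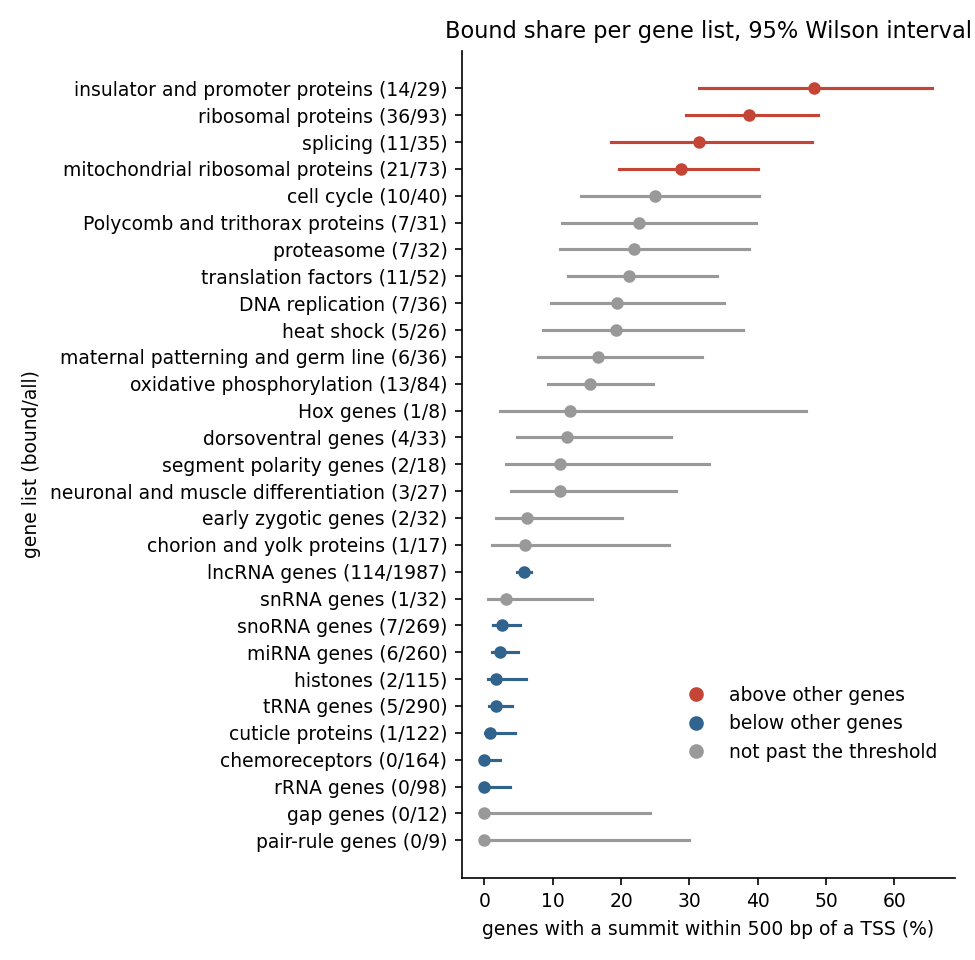
Share of genes bound in each of the 29 fixed lists, in percent, with 95% Wilson intervals and the bound and total number of genes. Insulator and promoter proteins (48.3%) and ribosomal proteins (38.7%) stand highest, and chemoreceptor, rRNA, gap and pair-rule lists are at 0.

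Divergently arranged genes were bound far more often than others. Of 5052 protein-coding genes whose TSS lay within 1000 bp of an oppositely directed TSS, 1364 were bound (27.0%, 25.8 to 28.2), against 620 of 8916 other genes (6.95%, 6.44 to 7.50), an odds ratio of 4.95 (Fisher's exact p = 5.9e-224). A summit between a pair of divergent TSSs counts for both genes, so the genes of a pair are not independent. A divergent gene can also be counted as bound through a peak at the TSS of its partner. That raises the share and the odds ratio by construction, and how far was not tested. The tests of gene lists did not take the arrangement of genes into account.

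Peaks were spread over the large arms with small differences in density. The X arm held 31.8 peaks per Mb, 1.14 times its share of the length (adjusted exact p = 0.00022), 3L held 30.1 (adjusted p = 0.027) and 2L 30.0 (adjusted p = 0.05 after rounding up), while 2R with 26.2 (adjusted p = 0.093) and 3R with 27.1 (adjusted p = 0.32) did not pass. Both 2R and 3R did pass, below the background, against the ranked peaks (adjusted exact p = 0.019 and 1.4e-05) and against the share of protein-coding genes (adjusted p = 2.4e-06 and 0.01). So did 2R with the left-out peaks put back (adjusted exact p = 0.021). The Y arm held 5 peaks, or 1.36 per Mb (adjusted exact p = 1.9e-36), and arm 4 held 0 (adjusted p = 2.8e-16). Each replicate alone had 2 peaks on Y, and replicate 1 alone had 1 on arm 4. Arm 4 had 17 ranked peaks, 12.6 per Mb against 1007 on X, and against the ranked peaks its call did not hold (adjusted exact p = 1), nor did that of X (adjusted p = 0.078). It is not known whether the lists used here hold every peak of arm 4, so the 0 is not read as an absence of binding. Against the share of protein-coding genes per arm, the calls of Y (adjusted exact p = 0.84) and 2L (adjusted p = 0.38) did not hold. The 3L call did not hold in replicate 1 alone (adjusted exact p = 0.36) or replicate 2 alone (adjusted p = 0.051), in the conservative list (adjusted p = 0.11), at an IDR of 0.001 (adjusted p = 0.21) or with the left-out peaks put back (adjusted p = 0.12). The 2L call did not hold in replicate 1 alone (adjusted exact p = 0.21).

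Of the 24 motifs, 9 were more frequent at summits than in flanks 500 bp away and 5 less frequent. The TATA word TATAAA lay in 34.8% of summit windows and 19.2% of flanks (adjusted exact p = 8.9e-51), and the promoter element Ohler 7 (CAKCNCTRNY) in 7.54% and 3.23% (adjusted p = 1.1e-16). The DNA replication-related element DRE (TATCGATA) lay in 2.22% and 0.574% (adjusted exact p = 1.6e-09), the BEAF word CGATA in 25.1% and 20.5% (adjusted p = 4e-06), and the pita/ZIPIC word in 4.30% and 2.66% (adjusted p = 0.00031). Each DRE also holds the BEAF word. The word CAGCCCTG (60 summit windows and 13 flanks) always holds the pita/ZIPIC word and fits the first 8 bases of Ohler 7. The calls of Ohler 7 and pita/ZIPIC are therefore not independent either. GATA words (35.8% and 30.0%, adjusted exact p = 3.5e-07), homeodomain words (17.1% and 12.4%, adjusted p = 1.8e-08), Ohler 1 (0.417% and 0.104%, adjusted p = 0.024) and Su(Hw) (0.495% and 0.183%, adjusted p = 0.041) completed the 9 motifs above the flank. Below it were the CA repeat (2.71% and 7.09%, adjusted exact p = 5.7e-18), the short Adf1 word (4.43% and 6.91%, adjusted p = 1.2e-05), GAGA (2.69% and 4.28%, adjusted p = 0.00036), the Twist E-box (7.22% and 9.60%, adjusted p = 0.0005) and the CACGTG E-box (1.69% and 2.45%, adjusted p = 0.041). The 10 others did not pass, among them Zelda (0.782% and 1.23%, adjusted exact p = 0.084), Dorsal (0.600% and 0.730%, adjusted p = 0.66), Bicoid (6.49% and 5.95%, adjusted p = 0.44), CTCF (7.30% and 7.69%, adjusted p = 0.66) and Pho (3.81% and 3.94%, adjusted p = 0.81), as well as TCT (adjusted p = 0.084), the relaxed Zelda word and Ohler 6 (adjusted p = 0.064 each), Ohler 5 (adjusted p = 0.81) and the long Adf1 word (adjusted p = 0.74). With 50 bp either side of the summit, pita/ZIPIC (1.33% and 1.15%, adjusted exact p = 0.64), Su(Hw) (0.64), Ohler 1 (0.2) and the Twist E-box (0.11) did not pass. Against flanks 1000 bp away, Ohler 1 (adjusted exact p = 0.09) and Su(Hw) (0.37) did not, while Zelda did, below the flank (0.037). Su(Hw) also missed the threshold in the conservative list (adjusted exact p = 0.22) and, with Ohler 1, at an IDR of 0.001 (0.074 and 0.14). With the left-out peaks put back, the CACGTG E-box did not pass (adjusted exact p = 0.11) and Ohler 6 did (0.046). In replicate 2 alone, Ohler 1 (adjusted exact p = 0.057), the CACGTG E-box (0.057) and Su(Hw) (0.21) did not pass and TCT did, below the flank (0.0099). In replicate 1 alone, TCT (adjusted exact p = 0.013), the relaxed Zelda word (0.0067) and Ohler 6 (0.011) passed.

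Summits were AT-rich, with a mean GC content of 34.3% within 25 bp of the summit and 45.1% at 300 bp on both sides, so the motifs were also compared at equal base composition. Against windows of equal GC content at ranked peaks that did not pass, a comparison chosen after seeing the data, Ohler 7 (3.18% in the matched windows, adjusted exact p = 3.5e-16), pita/ZIPIC (2.01%, adjusted p = 1.1e-07), DRE (1.25%, adjusted p = 0.0074), BEAF (20.7%, adjusted p = 3.5e-05), TATA (31.5%, adjusted p = 0.0089), GATA (33.2%, adjusted p = 0.043) and the CA repeat (4.17%, adjusted p = 0.0033) kept their direction past the threshold. Homeodomain (17.2%, adjusted exact p = 1), short Adf1 (3.96%, adjusted p = 0.5), Ohler 1 (adjusted p = 0.2), Su(Hw) (adjusted p = 0.52) and both E-boxes (adjusted p = 0.42 for Twist and 0.53 for CACGTG) did not pass. GAGA turned round, with 1.69% in the matched windows (adjusted exact p = 0.011). CTCF, which had not passed against the flank, passed above the matched windows (7.30% and 5.63%, adjusted exact p = 0.011). Base composition was not matched between the 1489 summits within 500 bp of a protein-coding TSS and the TSSs of protein-coding genes without a peak. Position was not matched either, since the windows were centred on these summits, up to 500 bp from a TSS, or on the TSS itself. A motif that keeps a set place relative to TSSs could differ for that reason alone. These summits held homeodomain words in 18.7% against 9.50% (adjusted exact p = 1.8e-22), TATA in 39.4% against 29.9% (adjusted p = 2.2e-12), Ohler 7 in 14.04% against 8.45% (adjusted p = 2.4e-10) and pita/ZIPIC in 7.79% against 3.88% (adjusted p = 7.3e-10). Ohler 1 lay below these TSSs, in 1.01% against 3.49% (adjusted exact p = 4e-08). DRE (5.44% against 6.96%, adjusted exact p = 0.058), BEAF (0.098), GAGA (0.52) and both E-boxes (0.53 for Twist and 0.28 for CACGTG) did not pass. GATA (adjusted exact p = 0.015), TCT (0.015) and Su(Hw) (0.537% against 0.134%, 0.0095) passed above. Short Adf1 (3.69% against 6.75%, adjusted exact p = 6.7e-06), Ohler 6 (0.0095) and the CA repeat (0.047) passed below.

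**Figure D4:**
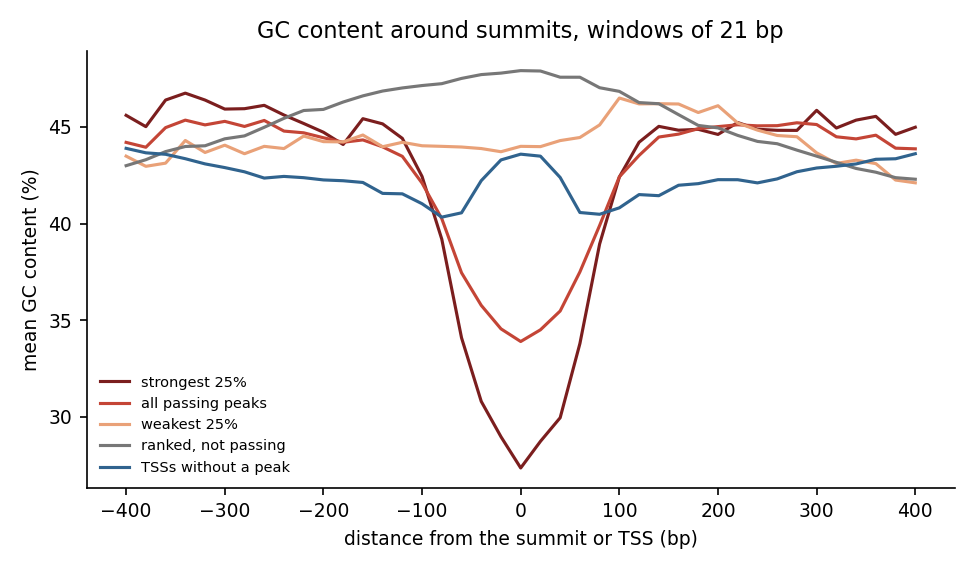
Mean GC content in percent, in windows of 21 bp, by distance in bp from the summit of passing peaks, of the 25% strongest and weakest of them, of ranked peaks that did not pass, and from TSSs without a peak. The vertical axis does not start at 0. Passing peaks dip to a minimum at the summit, the strongest more deeply, and ranked peaks that did not pass rise there.

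Among all words of 8 bases, CACTGAGA had the smallest p in the windows of 100 bp either side of the summit. It ranked number 3 in replicate 2 alone, 4 in replicate 1 alone and at an IDR of 0.001, and 99 with 50 bp either side of the summit (adjusted exact p = 3e-06). It lay in 182 of 3835 summit windows (4.75%, 4.12 to 5.47) and in 18 flanks (0.469%, adjusted exact p = 2.8e-31), and in 4.63% and 5.32% of the windows of the replicates' own lists (mean 4.98% ± 0.489, SD, n = 2). Other words with more than 1 G or C near the top were CACAGTGG (179 and 31 windows, adjusted exact p = 2.2e-23) and CACTGTGC (194 and 44 windows, adjusted p = 3.1e-21). Like CACTGAGA, both hold the bases CACTG on 1 of the strands. Of the words that passed above the flank, 59 held CACTG, so such words are not independent of each other. In all, 1823 words passed, 1139 above the flank and 684 below it, and 690 of those above had at most 1 G or C, led by ATTTAAAA (428 and 169 windows, adjusted exact p = 2.6e-24). The word CACTGAGA was more frequent in distal peaks (144 of 2243, 6.42%) than in TSS-proximal ones (38 of 1592, 2.39%, Fisher's exact p = 2.7e-09), a split made after seeing the data.

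**Figure D5:**
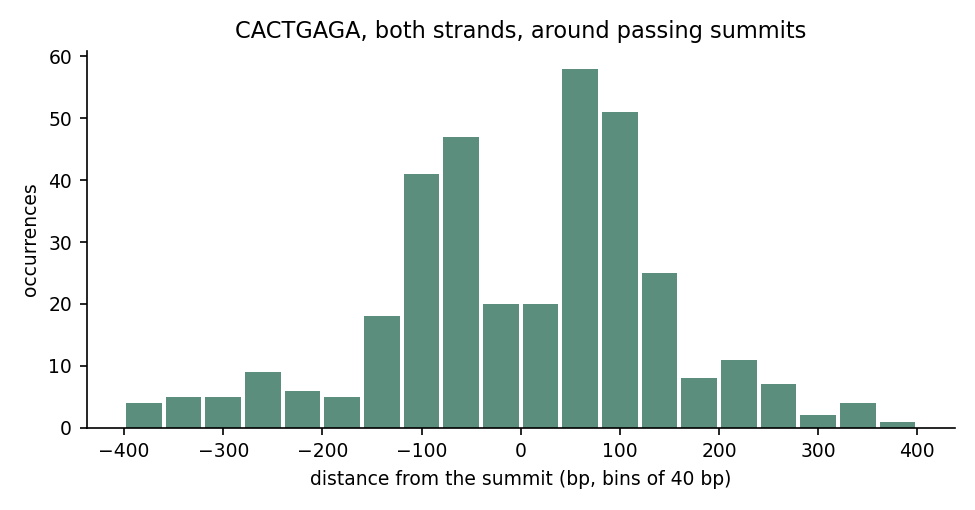
Occurrences of CACTGAGA on both strands by distance in bp from the 3835 summits, in bins of 40 bp. The bin from 40 to 80 bp on the side of higher coordinates holds the most, 58, and the bins next to the summit hold 20 each.

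Stronger peaks lay nearer to promoters. Among the 25% of peaks with the highest signal, 202 or more, 538 of 958 summits (56.2%, 53.0 to 59.3) were TSS-proximal, against 267 of 958 (27.9%, 25.1 to 30.8) among the 25% with the lowest, up to 80.4 (odds ratio 3.32, Fisher's exact p = 2.3e-36). In replicate 1 alone the odds ratio was 1.99 (Fisher's exact p = 7.1e-11). TATA (42.9% against 22.4%, adjusted exact p = 1.7e-20), homeodomain (20.6% against 12.4%, adjusted p = 9.1e-06) and GATA words (37.3% against 27.3%, adjusted p = 1.5e-05) were more frequent in the strongest peaks, although over all summits homeodomain words showed no excess against GC-matched windows (17.1% and 17.2%). The short Adf1 word (2.71% against 8.35%, adjusted exact p = 4.5e-07), the CA repeat (1.88% against 3.76%, adjusted p = 0.047) and the Twist E-box (5.64% against 8.46%, adjusted p = 0.047) were less frequent, and DRE, Ohler 7, BEAF, GAGA and the other motifs tested did not differ past the threshold. Base composition was not matched in these motif comparisons, and it differed, with a mean GC content within 25 bp of the summit of 28.3% in the strongest peaks and 44.0% in the weakest. The adjustment ran over the 14 motifs that had passed at summits.

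Peaks in the thresholded list of replicate 2 only were less often at promoters. Of its 432 such peaks, 112 (25.9%, 22.0 to 30.3) were TSS-proximal, against 985 of 2047 shared ones (48.1%, 46.0 to 50.3, odds ratio 2.65, Fisher's exact p = 7.5e-18). With a 50% reciprocal overlap as the rule for sharing, the odds ratio fell to 1.62 (35.8% against 47.4%, Fisher's exact p = 2.1e-07). In replicate 1, 412 of 894 unshared peaks (46.1%) and 1007 of 2063 shared ones (48.8%) were TSS-proximal (odds ratio 1.12, Fisher's exact p = 0.17). The difference between the replicates was not tested. Unshared peaks were weaker in both, with a median signal of 52.1 against 90.1 in replicate 2 and 53.4 against 102 in replicate 1. Signal was not matched in these comparisons. Of the 432 peaks, 92.8% overlapped the much longer ranked list of replicate 1 and 80.8% the optimal list. They are thus unshared only between the thresholded lists.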

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

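Of the tests given here, that of a filter on low signal was chosen after the result was seen. Some peaks with signal were left out of the report's comparisons, apart from the correlation of replicate signals and the alternatives with left-out peaks put back, and are given here for that reason. The thresholded optimal list used here lacked 205 ranked peaks with an IDR of 0.01 or less, 113 of them on the arms (52 on 3R, 32 on X, 24 on 2L, 3 on 3L and 2 on 2R). The strongest, named after their values were seen, lay in an intron of ush on 2L, 480895 to 481284, 1408 bp from the TSS of cbt (signal 2638), in an intron of Lk6 on 3R, 11760887 to 11761209 (1296), between CG18428 and eIF4EHP on 3R, 24108991 to 24109372 (1102), in larp (941) and between Sirt6 and pont (670).

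A filter on low signal is argued against by their median signal of 111 on the arms, above the 80.4 that bounds the weakest 25% of the peaks kept. Annotated transposons account for a small part at most, since 5.31% of these peaks (6 of 113, 95% interval 2.46 to 11.1) had their summit in one, more than the 0.469% of the peaks kept (Fisher's exact p = 4.3e-05). A list of regions set aside by position stays open as a possible explanation, because the kind of the further file is not given in the sources used here. Most of the left-out peaks on X lay between 23326803 and 23430235. Others lay in groups too, as on 3R between 9053776 and 9055967. This goes with such a list, but the grouping was not compared with that of the peaks kept. No biological explanation was tested. With these peaks put back, 41.2% of summits were TSS-proximal.

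A further 57 peaks of the optimal list lay on 41 sequences off the arms, all assigned to X, with a median signal of 103 and a highest signal of 760.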

How the results depend on the processing

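Of 95 alternative values of the results that answer a comparison, 89 kept their direction and side of the threshold, or stayed within their limits, and 6 moved; the IDR of 0.001, the GC-matched background, the return of left-out peaks and the mismatched list members put right were chosen after seeing the data. The planned stricter IDR of 0.01 equals the threshold of the authors and was not run as a change. At an IDR of 0.001 the optimal list fell to 2345 peaks and the conservative list to 2164, by construction. Over all ranked peaks the Spearman coefficient was 0.296. Arms past the threshold numbered 5, and 3 to 4 without 1 replicate. Motifs past it numbered 14, and 9 against GC-matched windows. Words past it numbered 1823, and 818 with 50 bp either side of the summit. Of 582 alternatives for single features, arms, lists and motifs, 517 gave the same verdict, 41 lost the threshold, 22 gained it and 2 reversed: Ohler 1 against TSSs without a peak (1.01% against 3.49%) and GAGA against GC-matched windows (2.69% against 1.69%). The Ohler 1 comparison sets windows centred on summits against windows centred on TSSs. Except where an alternative's construction is named, the cause was not tested. No paired analysis was possible because there is 1 group. Read depth was not used here, and the number of peaks and of genes per list limits the intervals.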

Other observations

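The GC and word analyses here were added after seeing the data, and of their tests those of promoter sequence and of transposons were chosen after the result was seen. The 25 peaks of highest signal found in both replicates had between 20.8% and 39.6% GC within 50 bp of the summit.

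GC content fell towards the summits of passing peaks. It averaged 34.3% within 25 bp of the summit and 45.1% at 300 bp on both sides, a difference of -10.8 percentage points (95% interval -11.3 to -10.3, 3835 peaks), and -13.2 ± 0.757 over the lists of the replicates (SD, n = 2). The strongest 25% of peaks differed by -17.3 points and the weakest by 0.166 (-0.909 to 1.24). A GC bias shared by all candidate peaks is argued against, since 10000 ranked peaks that did not pass differed by 4.03 points in the opposite direction, and so is promoter sequence as the whole cause, since distal peaks differed by -9.65 points and TSS-proximal ones by -12.4. A bias acting only on the strongest windows stays open without a control library, and no biological explanation was tested.

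CACTGAGA lay beside summits, with 98.5 occurrences per 80 bp of sequence at 40 to 120 bp from the summit, 40 at up to 40 bp and 7 at 320 to 400 bp. It is unlikely to mark copies of annotated transposons, which held the summits of 0% of the 182 peaks with the word (0 peaks, up to 1.65%). The GC content of the windows is unlikely to be the whole cause. GC-matched windows of ranked peaks that did not pass held the word in 1.36% (52 of 3835, odds ratio 3.62, Fisher's exact p = 1.4e-18). Without matching, such windows held it in 0.82% (82 of 10000), so GC content may go with part of the excess. Only the GC content of the windows was matched, not its fall towards the summit or the order of bases. A hypothesis of a fixed orientation fared well, as the GAGA end pointed to the summit in 246 of 264 occurrences within 140 bp (93.2%, 89.5 to 95.6). A hypothesis that its reverse complement TCTCAGTG marks transcription starts did not, with 8 sense and 8 antisense occurrences within 10 bp of annotated TSSs (50% sense, 28.0 to 72.0). The word ran on with A in 85.2% and 92.0% of cases at the 10th and 11th positions, so the orientation may partly reflect which side of the word is AT-rich, which the 93.2% cannot separate.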
